A study of Homo sapiens with 4 samples.

How the data were processed

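Total RNA of HCT116 cells was measured on 4 single-colour arrays, 2 of cells with a control shRNA and 2 of cells with an shRNA against PCAF, grouped by their sample titles. Biotinylated cRNA was prepared by the manufacturer's standard procedure, per the labels' protocols. The deposited values are log2 probe set signals for 33297 probe sets on each array. Affymetrix Expression Console and limma are named in the submitters' processing notes, without a role or version. The summarization and normalization methods and the genome annotation are not given in the sources used here. That the deposited values are on a log2 scale was read from their range (3.62 to 14.21). Scanner files were not used here, so background correction, array flags and scan batches were not checked. No 2 arrays held identical values.

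A second file is the authors' deposited table of up and down genes, with a probe set, a gene symbol, a value headed fold change and a p-value per line. The unit of the value headed fold change was tested against the arrays and is other than a fold: it is proportional to the log2 difference, so folds were computed here as 2 to the power of the log2 difference. The deposited p-values are unadjusted, as a comparison with the arrays showed, and no test is named for them in the sources used here. The table was the source of gene symbols. Of its 852 lines, 688 symbols matched a current RefSeq symbol (assembly GRCh38.p14, without regard to case), 122 matched the synonym of a single gene and were updated, 12 matched synonyms of several genes and 30 matched none, and these last groups kept the file's symbol and so were matched to no gene list, except in an alternative chosen after seeing the data. Of the 759 probe sets, 711 had 1 symbol and 48 had several (up to 14). No single gene was named from a probe set with several. No coordinates are given, because no genome build is stated for the arrays.

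The difference of shPCAF minus shControl was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), on the values as deposited without further normalization or filter, and p-values were adjusted by Benjamini-Hochberg over all 33297 probe sets with a threshold of 0.05. The prior gave 2.73 degrees of freedom beside the 2 residual ones. Errors after a log2 difference are moderated standard errors, and errors after a group's signal are standard deviations over 2 arrays. Control probe sets were to be left out, but the files do not mark them. The 4201 probe sets with the lowest identifiers, which hold 24 lines of the authors' table, form a block that the files do not describe. They were kept, and leaving them out was tried as an alternative chosen after seeing the data.

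The tests, the gene lists and the rule for naming genes were fixed before the data were examined, apart from the changes given here. The genes named in the text follow that rule, apart from those listed here as exceptions. The rule takes the 12 largest rises and the 12 largest falls among probe sets with 1 symbol, an adjusted p below 0.05 and both shPCAF arrays beyond both shControl arrays, up to 4 members with 1 symbol and the smallest p of each described gene list, the 3 largest values in each direction of the authors' table, and KAT2B, KAT2A and CDKN1B, of which no probe set is named. A gene among the largest rises that this rule takes is not reported here. ASNS, DDIT3, PHGDH, CEBPB, CEBPG, CDC20, SKP2, PGAM1, PSMB2, HSPA13, CLGN, ADRM1, the older symbols SARS, GARS and HIST1H2BE and the genes first named in the closing section stand outside that rule and were chosen after their values were seen.

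A test of 35 gene lists by camera had been planned over all genes. It needs a gene for every probe set, and was replaced by Fisher's exact test of the split into higher and lower members against the other named probe sets, for lists with at least 5 probe sets in the table, counting each probe set once if any of its symbols is in the list (scipy 1.17.1, statsmodels 0.14.6, Python 3.11.15). The limma fit was tested on simulated arrays with the real means and the fitted variance prior. With 4000 of 33297 probe sets changed, it recovered 87.6% of log2 changes of 0.7 and 98.6% of changes of 1.5, with 4.73% false calls. With 200 changed it recovered 6% and 87%. The simulated errors followed limma's own model, independent between arrays and equal in both groups. The shares recovered and falsely called may therefore differ for the real arrays. The list test called 99.5% of simulated lists of 12 members turned mostly down and 1.5% of unchanged ones, over 200 draws. Lists of other sizes, lists turned up and members that move together were not simulated, so these shares do not carry over to them.

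Alternatives were quantile normalization, median centring, leaving out the dimmer probe sets, the replicate number as a block, an intensity trend with a robust prior, array weights, another threshold, and leaving out each array in turn. The replicate numbers of the labels are not stated to mark shared cultures or days.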

Results

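The study asked how the transcriptome of HCT116 cells, an established human colorectal carcinoma line, differed after short hairpin RNA (shRNA) knockdown of PCAF. PCAF is the lysine acetyltransferase now named KAT2B, a transcriptional coactivator that acetylates histones and other proteins. The title of the series ties the experiment to target genes of p27 (CDKN1B), an inhibitor of cyclin-dependent kinases. Total RNA from asynchronously growing cultures was hybridised to 4 single-colour Affymetrix arrays, 2 from cells that received a control shRNA (shControl) and 2 from cells that received the PCAF shRNA (shPCAF). Each array gave a log2 signal for 33297 probe sets, with medians of 7.08 and 7.10 in the shControl arrays and 7.03 and 7.02 in the shPCAF arrays. Arrays of one group correlated more closely (Pearson r over probe sets 0.997 for shControl and 0.995 for shPCAF) than arrays of different groups (0.987 to 0.989). With 2 arrays per group the number of arrays limits the precision of every value. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

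Gene symbols were paired with probe sets only in the authors' deposited table of up and down genes, which names 759 of the probe sets. No line of that table carries KAT2B, KAT2A or CDKN1B. The level of the shRNA target, of its paralogue and of p27 was therefore not analysed here, and the knockdown itself has no check in these values. All gene names below come from that table, which was selected on the same 4 arrays.

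Expression differed widely between shPCAF and shControl cells. By limma's moderated test with Benjamini-Hochberg adjustment, 2346 probe sets were higher and 1948 lower in shPCAF cells at an adjusted p below 0.05. Large rises outnumbered large falls: 351 of the called probe sets rose and 139 fell by at least 1 on the log2 scale, and 34 rose and 3 fell by at least 2. Of all 4294 called probe sets, 17.7% carry a gene name here. The split between higher and lower calls depended on how the arrays were centred, since 54.6% of calls were higher on the values as deposited and 68.0% after each array was centred on its median, when 3012 probe sets were higher and 1419 lower. No probe set passed when either shControl array was left out, where the lowest adjusted p was 0.0767 without replicate 1 and 0.0839 without replicate 2, although by limma 6848 and 6849 probe sets still had an unadjusted p below 0.05. The calls numbered 1933 without shPCAF replicate 1 and 2363 without shPCAF replicate 2.

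Among probe sets with a single symbol, the genes with the largest rises included 3 of the list of ATF4 and amino acid response genes, CHAC1, DDIT4 and SLC7A11. LURAP1L (listed under its older symbol C9orf150) rose most, from a log2 signal of 7.24 ± 0.02 (SD, n = 2) to 11.09 ± 0.06 (SD, n = 2), a 14.4-fold difference. TCP11L2 rose 11.4-fold, by 3.51 ± 0.18 (SE) on the log2 scale. CHAC1, a glutathione-degrading enzyme induced by the integrated stress response, rose 9.27-fold, from 8.24 ± 0.13 to 11.45 ± 0.10 (SD, n = 2 each). DDIT4, an inhibitor of mTORC1 signalling, rose 5.67-fold, and SLC7A11, the cystine and glutamate exchanger, rose 5.18-fold. SPX, which encodes the neuropeptide spexin (listed as C12orf39), rose from signals of 5.10 and 5.27 in the shControl arrays, below those arrays' lower quartiles of 5.48 and 5.50, to 7.97 and 7.78 in the shPCAF arrays. Whether its shControl signal was above background was not measured, so its 6.48-fold difference may understate the change. NT5E, the cell surface nucleotidase CD73, rose 6.05-fold and SLFN5 rose 5.87-fold. ABCC3, an organic anion efflux transporter, rose 5.55-fold. AHNAK2 rose 5.16-fold. LAMP3 rose 8.21-fold, but its probe set lies in a block of low identifiers that the files do not describe. In each of these genes both shPCAF arrays exceeded both shControl arrays, and the adjusted p (limma) lay between 0.00303 for LURAP1L and 0.00842 for DDIT4.

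The largest falls among probe sets with a single symbol were smaller than the largest rises and included a histone and CDCA3, of the mitosis list. H2BC14 (listed as HIST1H2BM), a replication-dependent H2B histone, fell most among them, from 13.44 ± 0.13 to 11.72 ± 0.04 (SD, n = 2 each), a 3.30-fold difference. NMU and GAL, which encode the neuropeptides neuromedin U and galanin, were 2.91-fold and 2.65-fold lower. TAF9B, a paralogue of the TFIID and SAGA subunit TAF9, was 2.91-fold lower, falling by 1.54 on the log2 scale with an SE of 0.067. CDCA3, a cell division gene, was 2.84-fold lower, and SPAG5, which encodes the mitotic spindle protein astrin, was 2.48-fold lower. ANAPC5, a subunit of the anaphase-promoting complex, was 2.53-fold lower, on a probe set of the same undescribed block. COMMD4 was 2.53-fold lower, MFSD2A 2.52-fold, BSCL2 (seipin, a protein of lipid droplet formation) 2.50-fold, the spliceosomal cyclophilin PPIH 2.45-fold and the alpha-tubulin TUBA4A 2.44-fold. The adjusted p of these 12 genes (limma) lay between 0.00715 for TAF9B and 0.0106 for GAL.

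**Figure D1:**
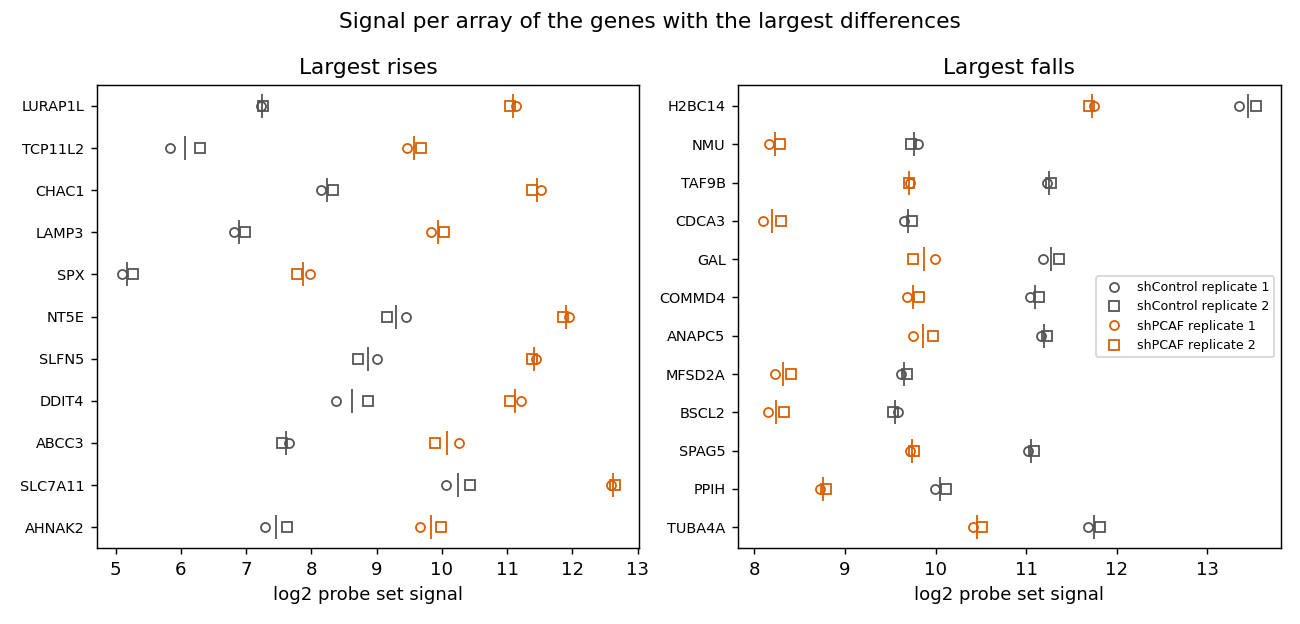
Log2 probe set signal (horizontal axes) of 11 genes with the largest rises and the 12 with the largest falls, with a circle for replicate 1, a square for replicate 2 and a vertical tick for the mean of each group. The shPCAF arrays lie above both shControl arrays for every gene on the left and below both for every gene on the right, with LURAP1L moving from 7.24 to 11.09.

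Of 35 gene lists fixed beforehand, 11 had at least 5 probe sets in the authors' table. Each was tested for whether its members leaned further to one direction than the other named probe sets did (Fisher's exact test, two-sided, Benjamini-Hochberg over the 11 lists), against a table in which 522 probe sets were up and 237 down. Of all probe sets that differed by at least 0.7 on the log2 scale, 958 were higher and 671 lower. The table thus leans further up, and against it a list of falls passes more easily than a list of rises. The lean of 6 lists passed. All members found in the table passed limma's test, both adjusted over all probe sets and adjusted over the list alone. As the table was selected on these arrays, that is not independent evidence of a change. The test treats genes as independent, which members of one pathway are not.

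The named genes of the ATF4 and amino acid response rose together. All 17 members matched in the table, of 35 in the list, were higher in shPCAF cells, with a median rise of 1.76 on the log2 scale (Fisher's exact test, adjusted p = 0.00529). The table also holds the older symbols SARS and GARS, each shared by several current genes of which 1 is in the list, and with their probe sets, both higher, the count was 19 of 19 (Fisher's exact test, adjusted p = 0.00284), an alternative chosen after seeing the data. CHAC1 led the list. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by 2.14 ± 0.08 (SE), STC2 (stanniocalcin-2) by 2.06 ± 0.09 and the pseudokinase TRIB3 by 1.94 ± 0.08. ASNS, which makes asparagine, rose 4.12-fold, and DDIT3, the transcription factor CHOP, rose 4.26-fold. The serine synthesis enzyme PHGDH rose 2.72-fold, and CEBPB and CEBPG, which encode C/EBP transcription factors, rose 2.79-fold and 2.96-fold. Among the unfolded protein response genes, 3 of 25 were in the table and all 3 were higher: HERPUD1 rose 2.55-fold, DNAJB9 2.18-fold and SEL1L 2.04-fold. That list was too short in the table for a test.

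The named genes of DNA replication and mitosis fell together. The mitosis list held 47 genes, the G1/S and replication list 44 and the histone list 48. Members outside the table have no value here. All 13 members of the G2/M and mitosis list in the table were lower, with a median of -1.04 on the log2 scale (Fisher's exact test, adjusted p = 2.34e-06). The kinesin KIF20A fell by 1.26 with an SE of 0.077, and FOXM1, a transcription factor of mitotic genes, was 2.33-fold lower. PLK1, a mitotic kinase, was 2.06-fold lower, and CDC20, an activator of the anaphase-promoting complex, was 1.95-fold lower. All 8 members of the G1/S and DNA replication list in the table were lower, with log2 differences from -1.22 to -0.73 (adjusted p = 0.000458 by Fisher's exact test). Of these, GINS2, a subunit of the replicative helicase, was 2.32-fold lower, ORC1, of the origin recognition complex, 2.13-fold, E2F2 2.06-fold and POLE2, a subunit of DNA polymerase epsilon, 2.12-fold. All 5 probe sets matched to the replication-dependent histone list were lower, with a median of -1.12 (Fisher's exact test, adjusted p = 0.00529). A further probe set of 5 older H2B symbols such as HIST1H2BE, each shared by several current genes, fell by 1.26 on the log2 scale and made the count 6 of 6 under the same alternative (Fisher's exact test, adjusted p = 0.00195). Apart from that of H2BC14, these histone probe sets are each listed under 2 to 14 gene symbols, so they cannot be assigned to single histone genes. Without the probe sets of several symbols the histone list had too few members for a test. Of the cyclins, CDKs and CDK inhibitors, 4 members in the table were lower and 1 higher, a lean that did not pass (Fisher's exact test, adjusted p = 0.0553) but did with the block of low identifiers left out (adjusted p = 0.0484), an alternative chosen after seeing the data. CDK1 was 1.73-fold lower, SKP2, the ubiquitin ligase subunit that targets p27, 1.76-fold lower, and CCND3 1.89-fold lower, whereas RBL2, the retinoblastoma-related protein p130, was 2.24-fold higher. CDK1 is also among the 13 members of the mitosis list.

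The members of the heat shock and proteasome lists in the table were also lower. The full lists held 30 and 33 genes, and members outside the table have no value here. All 6 heat shock list members in the table fell (Fisher's exact test, adjusted p = 0.00244), among them HSPH1 at 2.39-fold, the HSP90 co-chaperone AHSA1 at 2.29-fold and HSPE1, the mitochondrial chaperonin HSP10, at 2.06-fold. HSPA13 and CLGN, chaperone genes outside that list and chosen after their values were seen, were 2.09-fold and 3.63-fold higher. All 7 members of the proteasome list in the table fell (Fisher's exact test, adjusted p = 0.000998), among them PSMB6 at 2.05-fold and PSMA6 at 1.89-fold. ADRM1, a proteasome subunit outside the list and chosen in the same way, was 1.94-fold lower. Each of these lists has 1 probe set, of HSP90AB1 and of PSMB2, in the undescribed block of low identifiers.

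Other lists had 5 or more members in the table without a lean that passed. As most of the table rose, a list of 5 or 6 members cannot pass by rising: the p (Fisher's exact test, unadjusted) is 0.332 when 5 of 5 rise and 0.185 when 6 of 6 do, so the test says nothing against a rise of these lists. All 6 immediate early and MAPK feedback genes in the table, of 40 listed, rose (adjusted p of the lean = 0.226 by Fisher's exact test). JUN was 3.35-fold, the phosphatase DUSP5 2.97-fold and SPRY4 2.15-fold higher. All 6 epithelial junction and keratin genes in the table, of 38 listed, rose (adjusted p of the lean = 0.226 by Fisher's exact test). Among them, periplakin (PPL) rose 2.77-fold and E-cadherin (CDH1) 2.14-fold. All 5 p53 target genes in the table, of 39 listed, rose (adjusted p of the lean = 0.365 by Fisher's exact test). TNFRSF10B was 2.62-fold and SESN2 3.39-fold higher, and SESN2 is also a member of the ATF4 list. Of 34 listed hypoxia and glycolysis genes, 5 in the table rose and 1 fell (adjusted p of the lean = 0.671 by Fisher's exact test). NDRG1 was 3.22-fold and PDK1 2.42-fold higher, and PGAM1 was 1.74-fold lower. VEGFA, among the 5 that rose, is also a member of the ATF4 list.

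**Figure D2:**
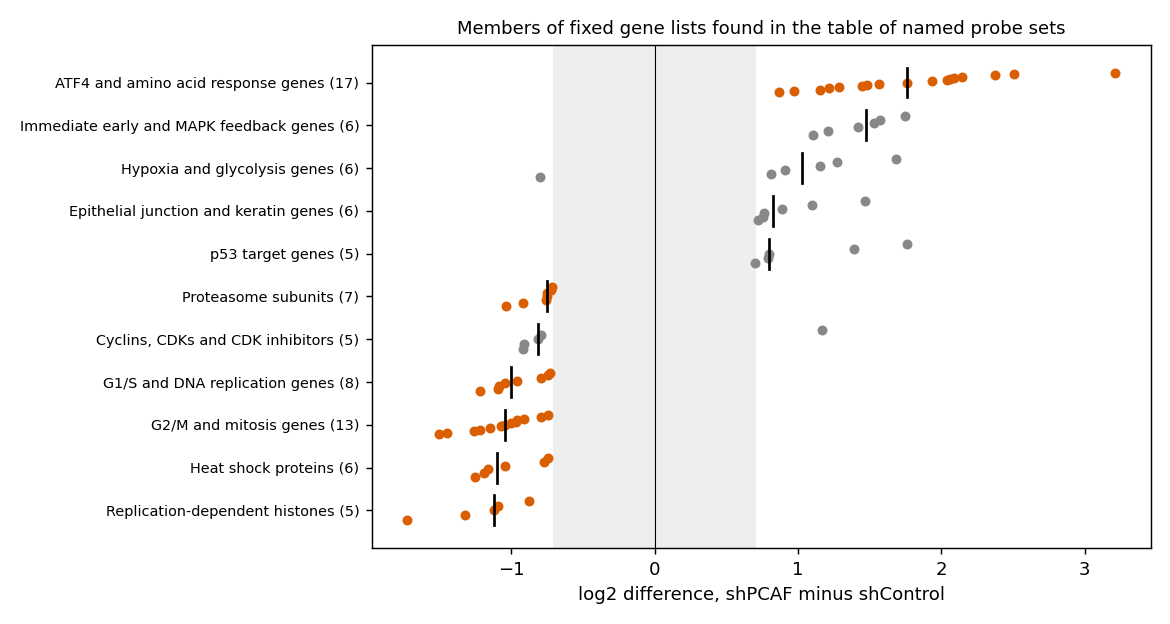
Log2 difference between shPCAF and shControl (horizontal axis) of each listed probe set of the 11 gene lists with at least 5 members in the authors' table, with the number of members in brackets and a vertical bar at the median; orange marks the 6 lists whose lean passed. The grey band from -0.7 to 0.7 holds no points because the table has no smaller difference; ATF4 members lie to the right of it and mitosis, replication, histone, heat shock and proteasome members to the left.

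The remaining lists had fewer than 5 members in the table and were not tested. TAF9B was the 1 member of 27 SAGA and ATAC complex subunits, and none of 28 other acetyltransferases and deacetylases was in the table. Of the oxidative phosphorylation genes NDUFS3, NDUFA2 and NDUFB10 were lower by 1.78- to 1.93-fold, NDUFA2 on a probe set of the undescribed block. Ribosome biogenesis genes had 2 members, both lower, and mitochondrial ribosomal proteins 1, also lower. Splicing factors, cytosolic ribosomal proteins, cholesterol biosynthesis, DNA repair, autophagy and lysosome, actin and TGF-beta response lists each had 2 to 4 members that went both ways. The only rising probe set of the splicing list and the only one of the cytosolic ribosomal list lie in the undescribed block. The 3 apoptosis regulators in the table (PMAIP1, BCL2L1 and BIRC3), the 2 NRF2 genes (ABCC3 and SLC7A11), the Notch pathway gene RBPJ and the NF-kB target BIRC3 were higher. No gene of the Wnt target, interferon-stimulated or intestinal differentiation lists was in the table. Among markers of other cell types, none of the macrophage or endothelial lists was in the table, the fibroblast list had TAGLN (1.66-fold lower) and ACTA2 (1.82-fold higher), and the lymphocyte list had CD22 (2.91-fold higher). Absence from the table means only that a gene was not named there, and is no measurement of it. Of 1629 probe sets that differed by at least 0.7 on the log2 scale, 1380 passed limma's test and 759 are in the table. A gene absent from the table may thus have differed as much as those in it.

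The authors' deposited table gives 557 lines as up and 295 as down. All 852 lines had the same direction in the values of the arrays, and all 759 probe sets passed limma's test, the largest adjusted p being 0.0296. The column headed fold change in the authors' deposited table does not hold folds of these values. In 852 of 852 lines it lay within 0.011 of 2.14 times the absolute log2 difference, whereas 367 lines lay within 5% of the fold that the log2 difference gives. The authors' deposited table thus lists LURAP1L at 8.24, TCP11L2 at 7.51 and CHAC1 at 6.87, where the log2 differences give folds of 14.4, 11.4 and 9.27. For the falls, the authors' deposited table lists H2BC14 at 3.68 and NMU and TAF9B at 3.30, where the log2 differences give 3.30, 2.91 and 2.91. The smallest log2 difference among probe sets of the authors' deposited table was 0.70, a fold of 1.62. The value in the authors' deposited table was above the fold in 530 lines and below it in 322, among them the 12 largest rises. The p-values in the authors' deposited table lay within 1e-05 of an unadjusted unequal-variance test on the same arrays in 709 of the 711 lines whose probe set has a single symbol. Of the 141 lines of the authors' deposited table on probe sets with several symbols, 47 did so, and each of those 48 probe sets was given different p-values on its different lines. A log2 difference of at least 0.7 and an unadjusted unequal-variance p below 0.05 were met by 846 probe sets, of which 759 were in the authors' deposited table. After Benjamini-Hochberg adjustment of that unequal-variance test, an alternative chosen after seeing the data, no probe set passed, against 1870 higher and 2000 lower at an unadjusted p below 0.05.

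**Figure D3:**
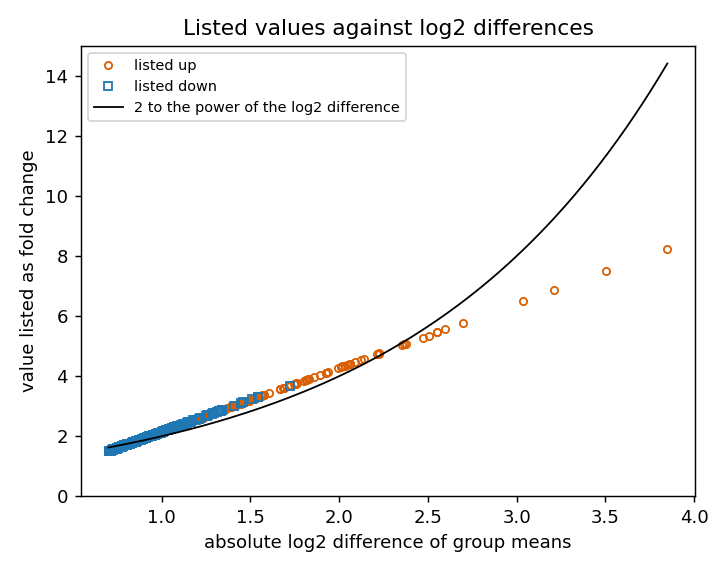
Value listed as fold change (vertical axis) against the absolute log2 difference of group means (horizontal axis) for each of the 759 probe sets of the authors' table, circles for up and squares for down, with the line showing the fold that each log2 difference gives. The points follow a straight line and not the curve, and the farthest point, LURAP1L, is listed at 8.24 where the curve is at 14.4.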

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

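The unequal-variance test, the removal of the low-identifier block and the list counts with probe sets of 1 symbol or with symbols shared by several genes were chosen after seeing the data. The counts of probe sets past the threshold ranged from 0 to 1227 higher and from 0 to 1142 lower when one array was left out, with 0 of the authors' 852 lines past the threshold without either shControl array and 801 and 837 without shPCAF replicates 1 and 2. With 1 shControl array left, that lone sample is assumed to vary like the shPCAF arrays, whose replicates differed more (SD of the replicate difference 0.223 against 0.184 for shControl), and 1 residual degree of freedom remains. The unequal-variance test with adjustment gave 0 higher and 0 lower, with a lowest adjusted p of 0.413. An unadjusted p below 0.05 with at least a 1.5-fold difference gave 1361 higher and 999 lower. The counts stayed within 1.5 times the main ones under quantile normalization (2456 and 2028), median centring (3012 and 1419), the filter on dim probe sets (3039 and 2670), the trend with robust prior (2521 and 2144), array weights (2353 and 1958) and removal of the low-identifier block (2950 and 2369). The samples share only a replicate number. The differences of replicate 1 minus replicate 2 in shControl and in shPCAF correlated at 0.25 over probe sets. The replicate block gave 2454 higher and 2130 lower and changed no call of a gene list or named gene. The 6 gene lists passed in each refit, as they depend only on the signs of the differences, and the count was 7 without the low-identifier block, 5 with probe sets of 1 symbol and 6 with symbols shared by several genes. All 852 lines kept their direction in each refit that tested them, 808 being left by the dim filter and 828 by removal of the block. Of the 94 genes that the top and list rules take, none changed direction. All 94 lost their call without either shControl array and under the unequal-variance test, with little change in size: the log2 differences moved by a median of 0.053 and by at most 0.24 without a shControl array, and the unequal-variance test alters only the error. CDK1 alone lost its call without shPCAF replicate 1, at -0.71. The KAT2B value, the count of genes in place of probe sets, camera with a preset or an estimated correlation, fry and the mean over a gene's probe sets were not run, because most probe sets have no gene name here. Signal over background is not given in the values, so its limit on dim probe sets was not checked.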

Other observations

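The tests of the signal-dependent offset, of the cell cycle hypothesis, of the listed fold changes and of the array splits, and the genes of the next paragraph, were chosen after the results were seen.

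Several integrin genes of the table rose. ITGB4 was 3.51-fold, ITGA2 2.93-fold, ITGA3 2.68-fold and ITGA6 2.23-fold higher. PLAU, the urokinase plasminogen activator, rose 4.35-fold. As these and the following genes were picked from the table after its values were seen, a test of them as groups would be void and is not given. The 5 HOX genes in the table (HOXA2, HOXA4, HOXA11, HOXB8 and HOXC5) all fell, by 1.63- to 2.10-fold, and apart from HOXB8 their shControl means lay between 6.93 and 7.28, near the arrays' medians. Of the histone demethylases, KDM7A (listed as Jhdm1d), KDM4C and KDM5A rose 4.17-fold, 1.74-fold and 1.64-fold. The aminoacyl-tRNA synthetase genes CARS1 and AARS1 rose 3.18-fold and 2.44-fold.

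The probe set with the largest rise among those without a name and outside the low-identifier block, 7922846, rose by 2.45 ± 0.19 (SE) on the log2 scale, and the one with the largest fall, 8134339, fell by 2.28 with an SE of 0.37. Within the low-identifier block 421 of 4201 probe sets passed the threshold, against 3873 of 29096 others.

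The rise of the 17 matched ATF4 list probe sets and the fall of the 26 matched probe sets of the replication, mitosis and histone lists stood together. An offset shared by probe sets of like signal was too small to account for it. In bins of like signal, the median difference of all probe sets lay between -0.107 and 0.015 on the log2 scale. Every probe set of the table differed by at least 0.70. Subtracting the bin medians could therefore change little, and the median size of these 43 probe sets was 1.15 before and 1.16 after. A hypothesis is that the shPCAF cultures may have held fewer cells in S, G2 and M phase, and fewer cells in S, G2 and M phase would leave few of the 26 probe sets higher. The number higher was 0, but that restates the pattern that raised the hypothesis, and the table holds no smaller differences, so the count leaves it open. The design cannot separate an effect of the knockdown from an unequal density or nutrient state of the cultures, or from an off-target hairpin effect. Each condition is represented by 2 arrays, the labels name only 1 shPCAF group and the level of the target gene was not analysed here. These alternatives remain open and untested.

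One deviating array as the source of the 4294 called probe sets is argued against by single-array differences, although no probe set passed without either shControl array. Differences taken from disjoint pairs of one shPCAF and one shControl array correlated at 0.747 over all probe sets when paired by replicate number and at 0.611 when crossed. A separate question was whether the calls could arise by chance from any grouping of the 4 arrays. Of the 3 splits of the 4 arrays into equal groups, 1 (the real one) gave as many calls, and the highest of the others gave 0. With 3 splits no share below 0.05 can be reached. In the other splits each group holds 1 shPCAF and 1 shControl array, so the difference between conditions adds to the spread within groups. That lowers their calls, so the splits do not decide whether the calls arose by chance.

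The values headed fold change in the authors' deposited table are a further pattern. That they are folds computed from the deposited signals is excluded by the 367 of 852 lines within 5% of such folds. The absolute log2 difference times a constant reproduces them, since all 852 lines lay within 0.011 of 2.14 times it. The origin of that constant stays open.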
